A study of Mus musculus with 16 samples.

How the data were processed

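R7T1 cells, a mouse pancreatic beta-cell line, were treated with a DMSO vehicle, the compound listed as BayK8644(2a), exendin-4, or both agents together, and were sampled after 0.5, 2, 6 and 24 h. BayK8644 is a dihydropyridine that keeps L-type calcium channels open, and exendin-4 is a peptide that activates the GLP-1 receptor. The labels do not explain the 2a, and the compound was taken to be BayK8644, on which every BayK8644 result depends. The doses were not given in the sources used here. The series held 16 arrays, 1 for each of the 4 treatments at each of the 4 times, so no treatment and time had a replicate. Per the labels' protocols, total RNA was isolated with RNeasy columns, its integrity was read on an Experion instrument, and 5 ug went through an Affymetrix single amplification with a biotin label. The labels do not say that arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

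Each array is 1-colour and gives an intensity for each of 45101 probe sets. The deposited values are linear intensity values made with GCRMA, per the submitters' processing notes, a method that corrects background by probe sequence, quantile-normalizes arrays and summarises probes into probe sets. Its version, the scanner and further steps were not given in the sources used here. Median intensity per array lay between 10.5 and 11.6 and the 75th percentile between 523 and 556, and between 46.6 and 47.6% of probe sets reached the filter level described next. The number of arrays limits the precision. Log2 of the deposited intensity was taken with no pseudocount and no further normalization.

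Probe sets were named from the platform annotation, in which 34958 had 1 gene symbol, 932 had several and 9211 had none. The 64 Affymetrix control probe sets were left out of the gene tests. Of those with 1 symbol, 34754 matched a record of the reference gene table used here, by gene identifier, and 0 symbols differed from that table, which can itself be older than current names. Probe sets with several or no symbols were kept out of the gene tests. A probe set was kept where its log2 value reached 4 (an intensity of 16) on at least 2 of the 16 arrays, which 21724 of them did. Of the 18193 genes with a probe set, 9010 had more than 1, and the probe set with the highest mean over the arrays stood for the gene. This left 10609 genes. Values under log2 4 lie near the background floor of the method, so a rise from there has a size that the floor sets in part. Of 325 called results for the genes named here, 17 had every array of their lower side under that level. Of the 325, 116 had more than 1 probe set of the gene above the filter, and in 11 of these 116 the probe sets differed in sign.

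Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), and adjusted p-values are Benjamini-Hochberg values over the genes tested, with 0.05 as threshold. The model over all times held time and treatment, with 9 residual degrees of freedom. There the 4 times stood in for replicates of a treatment, so an effect that changed with time counted as error. A further model gave each agent an effect at each time. It set the 2 arrays with the agent against the 2 without it at that time, assumed the effects of the agents to add up, and had 4 residual degrees of freedom. Its error was pooled over the times, although residuals were smallest at 0.5 h (root mean square 0.051) and largest at 24 h (0.092). The joint test of an agent over the 4 times, the simulation of the agents' correlation with no effect and the correlation of effects from different times were chosen after the data were seen. Differences are log2 values with limma's standard error (SE). The labels carry no replicate numbers that could pair arrays, and time was the only block.

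Lists of genes were tested with limma's camera, with a preset correlation between genes of 0.01, and adjusted over 320 tests (20 lists, 16 comparisons). With the correlation estimated from the residuals, 2 of the 99 list calls held, and the adjusted p from that setting is given beside each call. Counts of members that rose or fell use the adjustment over all genes, and counts "adjusted over the list alone" use only the list's members. The lists covered immediate-early genes, CREB and cAMP targets, calcineurin and NFAT targets, MAP kinase feedback genes, G1/S and replication genes, G2/M and mitosis genes, cell cycle inhibitors, beta-cell identity genes, secretory granule and exocytosis genes, calcium channels and calcium handling, insulin, IGF and AKT signalling, the unfolded protein response, sterol biosynthesis, glycolysis and hypoxia, apoptosis and survival, circadian clock genes, alpha, delta and PP cell markers, acinar and duct cell markers, mesenchymal, endothelial and leukocyte markers, and control genes used as references.

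The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison over all times, the 10 largest rises and the 10 largest falls among called genes that moved the same way at all 4 times, at single times the 5 largest of each, up to 4 members of each called list with the smallest p, and a fixed set of genes whether or not they passed, 15 of which were tested. Of the fixed genes, Ins1 and Mafa had no probe set with a single symbol and were not analysed here, and Glp1r did not reach the filter. Genes named outside the rule are marked as such. Alternatives were no filter, quantile normalization, eBayes without trend and with robust settings, all probe sets in place of 1 per gene, only the arrays compared, no time term, and leaving out each array or each time in turn. Where an array was left out of the model with an effect per time, the lone array that remained was assumed to vary like the others.

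The scripts were tested on data simulated for 10609 genes from the arrays' own means and variances, 5 times per model, with 200 genes changed. For BayK8644 against DMSO over all times, 85.7% of changes of 0.5 on the log2 scale and 100% of changes of 1 and of 2 were recovered, and 4.5% of calls were false. For BayK8644 at 2 h the shares were 58.2%, 96.4% and 100%, with 5.5% false calls. In 20 simulations of a list of 40 genes shifted by 0.3, camera found 20 such lists, and 2.6% of random lists had p under 0.05. Noise was simulated independently for each gene, and the list shift was equal at all times. These rates therefore do not cover lists whose members vary together. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.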

Results

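Gene expression was measured in R7T1 mouse beta cells under 4 treatments: the DMSO vehicle, the L-type calcium channel agonist BayK8644, the GLP-1 receptor agonist exendin-4, and the combination of both agents. Each treatment was sampled once at 0.5, 2, 6 and 24 h, which gave 4 arrays per treatment and 16 arrays in all. The title of the series names small molecules that induce expansion of beta cells. Levels are log2 GCRMA intensities, and 10609 genes were tested. Ins2, an insulin gene, had a mean log2 level of 15.69 ± 0.06 (SD, n = 4) on the DMSO arrays. Ins2 lay between 15.60 and 15.79 on all 16 arrays. Saturation of the signal at so high a level was not tested, so a rise of Ins2 could be missed. Pdx1, a transcription factor of beta cells, had a mean of 13.39 ± 0.02 (SD, n = 4). Glp1r, which encodes the receptor of exendin-4, stayed between 2.04 and 2.08 on all 16 arrays, near the floor of the method, so its level was not measured. Ins1 and Mafa were not analysed here. The 3' to 5' log2 difference of the Actb control probe sets, a measure of RNA integrity, lay between 0.59 and 0.80 on the 16 arrays.

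BayK8644 raised early response genes and feedback inhibitors of MAP kinase signalling. Npas4, a transcription factor induced by calcium influx, rose by 3.13 ± 0.21 on the log2 scale over DMSO (SE, n = 4 arrays each, 8.75-fold, adjusted p = 6.11e-06), from a mean level of 5.64 to 8.77. Spry1 and the phosphatase genes Dusp4 and Dusp6, which restrain MAP kinase signalling, rose by 2.32 ± 0.27, 1.62 ± 0.23 and 1.33 ± 0.15 (adjusted p = 0.00111, 0.00589 and 0.00094). The orphan nuclear receptor gene Nr4a1 rose by 2.04 ± 0.34 (adjusted p = 0.0167) and Egr1, an early response transcription factor, by 1.67 ± 0.31 (adjusted p = 0.0269). Further large rises were those of Fosb and Etv4, at 2.02 and 2.23, both from DMSO levels below 4, and of Rgs4 and Etv5, at 1.92 and 1.52. Falls were smaller. They were led by Cntrl (-0.68 ± 0.09), the unnamed transcript 4921524J17Rik (-0.68 ± 0.07), the growth arrest gene Gadd45a (-0.67 ± 0.11) and Endod1 (-0.64 ± 0.12). Txnip, which encodes a glucose-responsive inhibitor of thioredoxin, fell by 0.60 (adjusted p = 0.00356), and Slc40a1, Cldn1, Ypel5, 1700086P04Rik and Prnp fell by 0.57, 0.53, 0.49, 0.45 and 0.44. Ins2, Pdx1, Mki67, Irs2, Crem, Rcan1, Ccnd1, Igf1r, Cacna1c and Cacna1d did not pass, with differences between -0.10 and 0.12. Igf1r stayed between 3.93 and 4.21 on all arrays, near the filter level of log2 4. Ccnd1 was scattered between 3.70 and 5.22. For Igf1r and Ccnd1 the values therefore cannot show whether BayK8644 left them unchanged. Fos (2.29-fold, adjusted p = 0.151), Ccnd2 (0.50, adjusted p = 0.106) and Cdkn1a (0.22, adjusted p = 0.113) did not pass over all times either.

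By list, 7 of the 21 measured MAP kinase feedback genes rose with BayK8644 and 0 fell (9 rose when adjusted over the list alone), with a median of 0.18. This list passed with the preset correlation (adjusted p = 2.27e-10) and with an estimated correlation (adjusted p = 0.0335). Of 38 immediate-early genes 11 rose and 0 fell (19 and 1 adjusted over the list alone), Trib1 by 0.66 and Id1 by 0.77 among them (adjusted p = 1.34e-17 for the list, adjusted p = 0.115 with an estimated correlation). Of 30 CREB and cAMP targets 6 rose, among them the secretory peptide gene Vgf (1.17) and the small GTPase gene Gem (0.83), and 1 fell (8 and 2 adjusted over the list alone). The list passed (adjusted p = 6.17e-06, adjusted p = 0.230 with an estimated correlation). Of 14 calcineurin and NFAT targets, Npas4, Gem and Nr4a1 rose and 0 fell (adjusted p = 0.00378, adjusted p = 0.186 with an estimated correlation). All of these also belong to the immediate-early list, and Gem and Nr4a1 to the CREB and cAMP list. Calls of these lists are therefore not independent, here and at single times. Rcan1, a further member of the calcineurin and NFAT list, did not pass. In the unfolded protein response list Vldlr (0.33), Ddit3 (0.41) and Dnajb9 (0.45) rose of 37 measured, and 11 did when adjusted over the list alone (adjusted p = 2.89e-11, adjusted p = 0.302 with an estimated correlation). The sterol biosynthesis list had a median of 0.16 with 0 of 27 members past the threshold over all genes and 6 up and 1 down adjusted over the list alone (adjusted p = 4.84e-06, adjusted p = 0.552 with an estimated correlation). Of 59 G2/M and mitosis genes 0 passed over all genes, although 54 had negative differences and 22 fell when adjusted over the list alone (median -0.13, adjusted p = 1.11e-12, adjusted p = 0.460 with an estimated correlation). Prc1 (-0.23), Cdc20 (-0.18) and Racgap1 (-0.21), which act in cell division, had the smallest p-values of the list. Of 51 G1/S and replication genes Rpa2 fell by 0.29 and 0 rose (adjusted p = 2.3e-05, adjusted p = 0.552 with an estimated correlation).

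In total 89 genes passed in this comparison, 51 up and 38 down. Each of the 8 arrays compared moved the count by over 1.5 times when left out. DMSO at 0.5, 2, 6 and 24 h gave 305, 19, 20 and 32 genes, and BayK8644 at those times gave 251, 19, 16 and 20. Without the combination array at 0.5 h the count was 149. Without all arrays of 0.5, 2, 6 or 24 h the count was 591, 5, 5 and 17. Npas4, Spry1, Dusp4, Dusp6, Dusp5, Trib1, Id1, Gem, Vldlr, Cntrl, 4921524J17Rik and Txnip passed with each array left out in turn, and the other 17 of the 29 named genes called were lost without at least 1 array, with adjusted p up to 0.223.

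**Figure D1:**
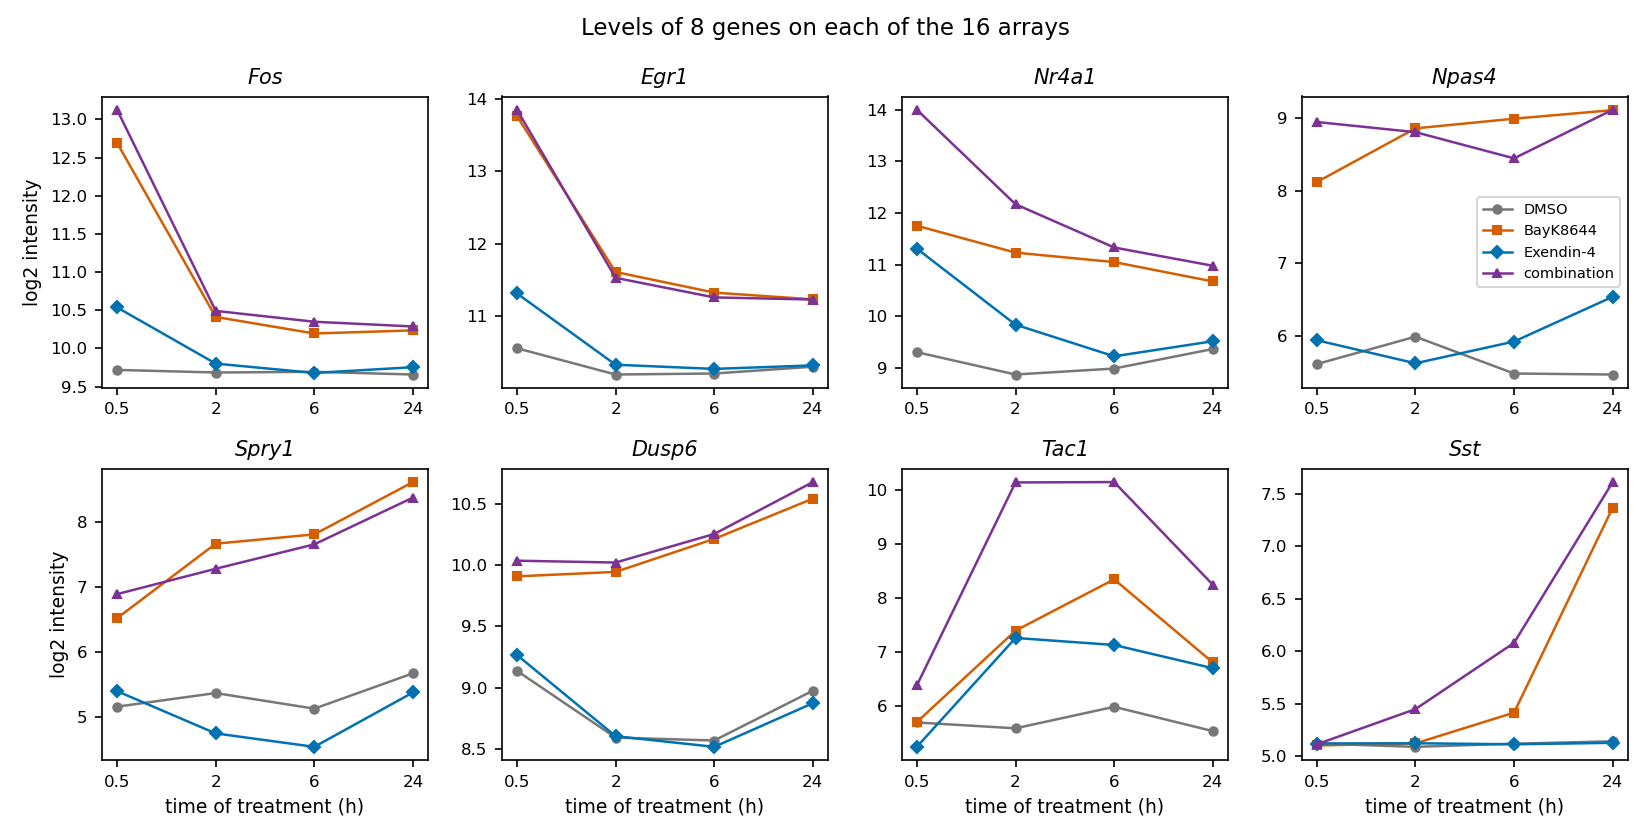
Log2 intensity (vertical axes) of 8 genes against time of treatment in h (horizontal axes, evenly spaced), 1 point per array, with lines joining the 4 arrays of a treatment. With BayK8644, Fos and Egr1 stand at 12.69 and 13.76 at 0.5 h and at 10.24 and 11.23 at 24 h, while Spry1 and Sst stand at their highest level at 24 h.

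The response to BayK8644 was also measured at each time, with the 2 arrays that held it set against the 2 that did not. At 0.5 h, 23 genes rose and 0 fell (limma, 218 genes at an unadjusted p under 0.05, where chance gives 530). The error is pooled over the times, and 12% of the residual sum of squares came from the arrays of 0.5 h against 25, 23 and 39% from those of 2, 6 and 24 h. Counts at different times are therefore not on 1 scale, since pooling makes the tests stricter at 0.5 h and more lenient at 24 h. The early response transcription factor genes Fos, Egr1 and Nr4a1 were among them. Fos rose by 2.78 ± 0.10 (6.88-fold, adjusted p = 1.33e-06), Egr1 by 2.87 ± 0.13 (7.31-fold, adjusted p = 1.12e-05) and Nr4a1 by 2.57 ± 0.08 (5.93-fold, adjusted p = 1.33e-06). Egr2 stood at 3.69 on the DMSO array, below the filter level, and at 8.05 with BayK8644 and 8.51 with the combination, a difference of 4.56 ± 0.16. Fosb (3.40), Npas4 (2.75), Spry1 (1.42), Dusp1 (1.01), Dusp6 (0.77) and Dusp4 (0.66) also rose. Of 38 immediate-early genes 16 rose, and 25 adjusted over the list alone (median 0.61, adjusted p = 6.9e-89, adjusted p = 0.0534 with an estimated correlation). Of the CREB and cAMP targets 7 rose, of the calcineurin and NFAT targets 5, and of the MAP kinase feedback genes 4. These lists passed (adjusted p = 3.79e-33, 1.48e-15 and 1.14e-18, adjusted p = 0.0744, 0.136 and 0.0626 with an estimated correlation). The glycolysis and hypoxia list (median 0.15) and the circadian clock list (median 0.06) passed with 0 members past the threshold over all genes (adjusted p = 3.7e-08 and 0.00805, adjusted p = 0.552 and 0.508 with an estimated correlation). Leaving out the 0.5 h array of DMSO or BayK8644 left 9 genes, leaving out that of exendin-4 or the combination left 6, and Egr2, Egr1, Fos, Nr4a1 and Gem passed each time.

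At 2 h, 122 genes rose and 51 fell. Npas4 (3.02 ± 0.28), Spry1 (2.41 ± 0.14) and Nr4a1 (2.34 ± 0.08) led, with Rrad, a small GTPase gene that rose from a DMSO level of 2.57 to 5.38, and Il4, a cytokine gene, which rose from 3.66 to 5.80. Abca1, the cholesterol export transporter, fell by 1.47 (adjusted p = 0.00403), and BC025920, Narf, Tfcp2l1 and Plekhh2 fell by 1.15, 1.14, 1.07 and 0.87. Tfcp2l1 fell to levels below 4. Of 27 sterol biosynthesis genes 10 rose and 0 fell (13 adjusted over the list alone). Msmo1 rose by 0.95, Idi1 by 0.89, Cyp51 by 0.65 and Sqle, a rate-limiting enzyme of the pathway, by 0.60 (list adjusted p = 1.68e-18, adjusted p = 0.149 with an estimated correlation). Of the unfolded protein response list 5 of 37 rose, Chac1 by 0.57, Ddit3 by 0.45, Mthfd2 by 0.41 and Xbp1, whose probe sets differed in sign, by 0.38 (adjusted p = 2.04e-11, adjusted p = 0.178 with an estimated correlation). Immediate-early genes had 13 members up and 1 down, CREB and cAMP targets 7 up and 1 down, MAP kinase feedback genes 8 up and 0 down, and calcineurin and NFAT targets 3 up and 0 down. These lists passed too (adjusted p = 1.14e-18, 6.94e-07, 1.42e-10 and 0.000242, adjusted p = 0.136, 0.287, 0.0938 and 0.469 with an estimated correlation). Kif2c and Prc1 fell among the G2/M genes (adjusted p = 2.67e-11 for the list, adjusted p = 0.290 with an estimated correlation). In the glycolysis and hypoxia list Adm rose by 1.62 and Txnip fell by 0.66 (adjusted p = 0.0338, adjusted p = 0.858 with an estimated correlation). The fixed gene Ccnd2, a cyclin of the G1 phase, rose by 0.51 ± 0.06. The count of 173 dropped to 50 without the 2 h array of DMSO or of BayK8644, to 19 without that of exendin-4 or of the combination, and to 87 without any 1 array of 0.5 h. Il4, Rrad, Spry1, Nr4a1, Gem, Maff, Vgf, Dusp4, Etv5, Dusp6 and Msmo1 passed each time.

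At 6 h, 180 genes rose and 82 fell. Il4 rose by 3.25 ± 0.25, to 7.02 and 7.43 on the arrays with BayK8644, Rgs4 by 3.10 ± 0.39, Npas4 by 3.01 ± 0.28 and Spry1 by 2.89 ± 0.14. Kcnh1, a potassium channel gene, rose from below 4 to 5.40 and 6.20. Abca1 fell by 1.63, Mapk15 by 1.11, the prostaglandin receptor gene Ptger3 by 1.08, Specc1 by 0.98 and Npr2 by 0.95. In the unfolded protein response list 13 genes rose and 0 fell (22 adjusted over the list alone), such as Creld2 (0.49), Chac1 (0.49) and Manf (0.37) (adjusted p = 3.5e-14, adjusted p = 0.136 with an estimated correlation). Sterol biosynthesis genes had 8 members up, Nsdhl (0.45) and Fdps (0.40) among them (adjusted p = 7.6e-08, adjusted p = 0.364 with an estimated correlation). MAP kinase feedback genes had 10 up, immediate-early genes 13, CREB and cAMP targets 7 and calcineurin and NFAT targets 3, each with 0 down. These lists passed (adjusted p = 1.77e-10, 3.8e-11, 2.72e-05 and 0.00809, adjusted p = 0.0938, 0.230, 0.391 and 0.591 with an estimated correlation). Among cell cycle inhibitors Gadd45a (-0.84), Mxi1 (-0.48) and Ccng2 (-0.52) fell. Among beta-cell identity genes Sytl4 (-0.48), whose probe sets differed in sign, and Nkx2-2 (-0.35) fell (adjusted p = 0.00134 and 0.0108 for these lists, adjusted p = 0.186 and 0.600 with an estimated correlation). Ncapd2, Racgap1 and Kif22 fell in the G2/M list, and Pola1 fell and Ccnd2 (0.70) rose in the G1/S list. Igfbp4 (0.67) rose and Foxo3 (-0.54) fell in the insulin, IGF and AKT list (adjusted p = 3.92e-08, 0.00115 and 0.0165 for these lists, adjusted p = 0.427, 0.691 and 0.691 with an estimated correlation). The count of 262 dropped to 29 without the 6 h array of DMSO or of BayK8644, to 38 without that of exendin-4 or the combination and to 125 without any 1 array of 0.5 h. It was 410 or 411 without any 1 array of 24 h. Of 41 named genes called at this time, 13 held each time, Il4, Npas4, Kcnh1, Spry1, Ccnd2 and Gadd45a among them.

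At 24 h, 316 genes rose and 225 fell. Kcnh1 (3.40 ± 0.27) and Il4 (3.27 ± 0.25) rose from levels below 4, followed by Npas4 (3.11 ± 0.28), Tmem212 (3.01 ± 0.34) and Spry1 (2.96 ± 0.14). Sst, the gene of the delta-cell hormone somatostatin and also a member of the CREB and cAMP list, rose by 2.36 ± 0.18 (5.12-fold, adjusted p = 0.000218). It stood between 5.09 and 5.14 on the DMSO arrays, at 7.37 with BayK8644 and at 7.61 with the combination at 24 h. Gcg, the glucagon gene of alpha cells, rose by 0.56 ± 0.10. Of the 6 measured alpha, delta and PP cell markers 2 rose and 0 fell at 24 h, and 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.00677, adjusted p = 0.460 with an estimated correlation). At 6 h Gcg was the member that rose, by 0.52 (adjusted p = 0.0397 for the list, adjusted p = 0.552 with an estimated correlation). In the same arrays the beta-cell transcription factor genes Nkx2-2 (-0.64 ± 0.06) and Myt1 (-0.39) and the granule protein gene Sytl4 (-0.56) fell, while Ins2 (0.01) and Pdx1 (0.00) did not pass. Of 32 identity genes 3 fell and 0 rose (adjusted p = 0.0403, adjusted p = 0.691 with an estimated correlation). Ccnd2 rose by 0.77 ± 0.06 and the p53-induced cell cycle inhibitor Cdkn1a by 0.34 ± 0.06, while Gadd45a fell by 1.07, E2f1 by 0.61, Cdk2 by 0.52 and Cdc25b by 0.55. Of 59 G2/M genes 11 fell and 0 rose (31 down adjusted over the list alone, median -0.20), and of 51 G1/S genes 6 fell and 1 rose (adjusted p = 4.04e-15 and 1.25e-06, adjusted p = 0.225 and 0.552 with an estimated correlation). Cell cycle inhibitors had 1 up and 4 down (adjusted p = 0.00785, adjusted p = 0.234 with an estimated correlation). The unfolded protein response list had 13 up, Sdf2l1 (0.73) and Ddit3 (0.52) among them, and sterol biosynthesis 2 up and 1 down (adjusted p = 2.35e-10 and 0.0205, adjusted p = 0.194 and 0.716 with an estimated correlation). Other probe sets of Ddit3 differed in sign. Immediate-early genes had 13 up and 1 down, CREB and cAMP targets 8 up and 1 down, and MAP kinase feedback genes 9 up (adjusted p = 2.13e-05, 0.00824 and 2.37e-06, adjusted p = 0.469, 0.591 and 0.136 with an estimated correlation). The largest falls were those of Sned1 (-1.25), Npr2 (-1.22), Pappa (-1.20), Mapk15 (-1.16) and Triobp (-1.08). The count of 541 dropped to 113 without the combination array and 125 without the exendin-4 array of 24 h and to between 271 and 274 without any 1 array of 0.5 h. Without the DMSO or the BayK8644 array of 24 h the count rose instead. The effect was then the combination against exendin-4, 1 array each. Without the exendin-4 or the combination array it was BayK8644 against DMSO, 1 array each. The model assumes these differences to be equal, yet they gave unlike counts, and the cause was not tested. Of 43 named genes called 19 held each time, Sst, Nkx2-2, Sytl4 and Ccnd2 among them. Gcg was lost at 24 h without the exendin-4 or the combination array of that time (adjusted p up to 0.146), and at 6 h without any 1 array of 0.5 or 6 h (adjusted p up to 0.314). Cdkn1a, E2f1, Cdk2, Cdc25b and Myt1 were lost at 24 h too (adjusted p up to 0.0903, 0.0928, 0.113, 0.0505 and 0.0646).

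**Figure D2:**
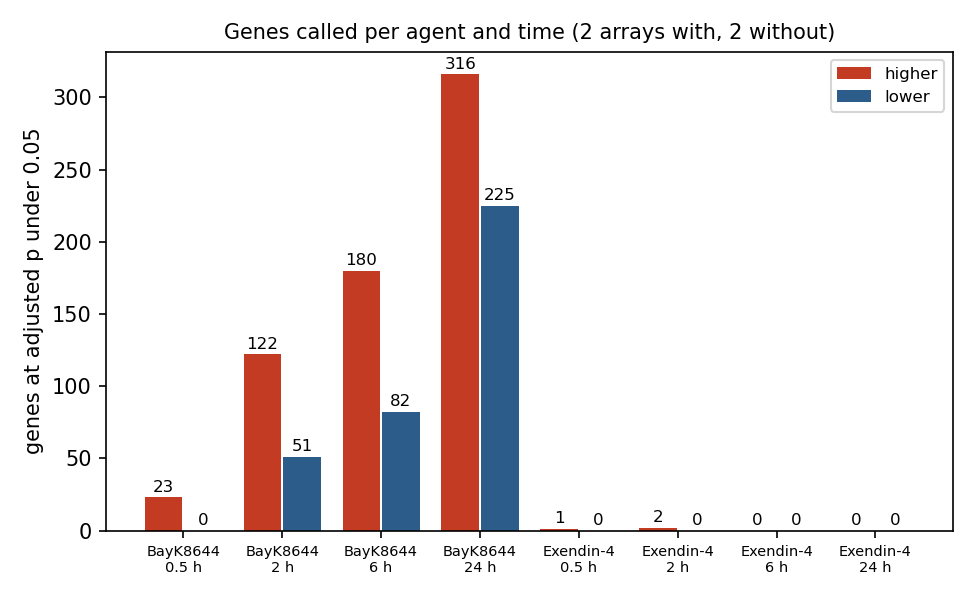
Number of genes at adjusted p under 0.05 (vertical axis) for each agent at each time (horizontal axis), from 2 arrays with and 2 without the agent, with red bars for genes higher and blue bars for genes lower with the agent. Bars for BayK8644 go from 23 higher and 0 lower at 0.5 h to 316 and 225 at 24 h, and those for exendin-4 stay at or below 2. Bars of different times are not on 1 scale, since the error is pooled over times.

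Exendin-4 alone against DMSO over the 4 times called 0 genes with limma, with 698 at an unadjusted p under 0.05 where chance gives 530, and the fit on all probe sets called 1. Genes of the cAMP pathway had differences that did not pass. Fosl2, an AP-1 component, differed by 1.11 ± 0.30 (adjusted p = 0.712, n = 4 arrays each, higher at 4 of 4 times) and Nr4a1 by 0.84 ± 0.34 (adjusted p = 0.751). Crem, a cAMP-responsive repressor, differed by 0.55 ± 0.21 (adjusted p = 0.737) and the cAMP phosphodiesterase genes Pde10a and Pde4b by 0.52 and 0.32. Ins2, Pdx1, Ccnd2, Irs2, Cdkn1a and Mki67 lay between -0.05 and 0.16. Of 30 CREB and cAMP targets 0 passed over all genes and 3 rose when adjusted over the list alone (median 0.16, adjusted p = 0.00134, adjusted p = 0.469 with an estimated correlation). The unfolded protein response list (median 0.05) and the G2/M list (median -0.04) also passed with 0 members called (adjusted p = 0.00319 and 0.00144, adjusted p = 0.716 and 0.772 with an estimated correlation). The call count stayed at 0 with each array and each time left out. The 698 did not hold, since it moved to 1103 without the exendin-4 array of 24 h and 1053 without the DMSO array of 0.5 h, and below chance to 432 and 460 without the DMSO array of 6 or 2 h.

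At single times, exendin-4 raised Nr4a1 by 2.12 ± 0.08 at 0.5 h (4.36-fold, adjusted p = 8.61e-06), from 9.31 to 11.31 without and from 11.75 to 14.00 with BayK8644. At 2 h Nr4a1 rose by 0.95 (adjusted p = 0.0102) and Ppargc1a, a coactivator of mitochondrial and fasting genes, rose from levels below 4 to 5.76 and 5.54 (adjusted p = 0.0476). These were the only genes called, and 0 were called at 6 h and at 24 h (limma, 738 and 626 at an unadjusted p under 0.05, where chance gives 530; 0 and 2 called without the filter on low values). With 1 array left out, those unadjusted counts ranged from 517 to 1290 at 6 h and from 456 to 1538 at 24 h, lowest without an array of 0.5 h and highest without 1 of 24 h. Other cAMP targets did not pass. Fosl2 differed by 2.03 ± 0.26 at 0.5 h (adjusted p = 0.114). At 2 h Tac1, the substance P precursor gene, differed by 2.20 ± 0.30 (adjusted p = 0.11), Crem 1.35 ± 0.20 (adjusted p = 0.129) and Pde4b 0.51 ± 0.07 (adjusted p = 0.11). The CREB and cAMP list was called at 0.5, 2 and 24 h, with 10, 10 and 0 members up adjusted over the list alone (adjusted p = 1.38e-18, 1.39e-09 and 0.0175, adjusted p = 0.124, 0.206 and 0.616 with an estimated correlation). Immediate-early genes had 12 members up adjusted over the list alone at 0.5 h (adjusted p = 3.99e-23, adjusted p = 0.125 with an estimated correlation). Further lists were called without any member past the threshold over all genes. They were MAP kinase feedback (median 0.09) and glycolysis and hypoxia genes (0.11) at 0.5 h, calcium channel and calcium handling genes (-0.06) at 2 h, and acinar and duct markers (0.24) at 6 h. G2/M genes at 2 and 24 h (-0.02 and -0.06), sterol biosynthesis genes at 2 and 24 h (0.08 and 0.07) and unfolded protein response genes at 2, 6 and 24 h (0.13, 0.08 and 0.08) were also called. For these lists the adjusted p with an estimated correlation was 0.230 or above. The calcineurin and NFAT list was called upward at 0.5 h, with Nr4a1 as the only member past the threshold over all genes. Its median was -0.01 and turned to 0.00015 after quantile normalization (adjusted p = 0.0417, adjusted p = 0.697 with an estimated correlation). The list was not tested without Nr4a1. Nr4a1 at 0.5 h passed with each array left out, and leaving out the 0.5 h array of DMSO or exendin-4 gave 2 genes. At 2 h the count of 2 dropped to 0 without any 1 array of 2 or 6 h and to 1 without any 1 array of 0.5 h.

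The combination was set against DMSO for the joint effect of both agents. Npas4 rose by 3.19 ± 0.21 (SE, n = 4 arrays each, 9.11-fold, adjusted p = 2.4e-06), Tac1 by 3.02 ± 0.43 (8.12-fold, adjusted p = 0.00288) and Nr4a1 by 2.98 ± 0.34 (7.92-fold, adjusted p = 0.000754). Tac1 reached 10.14 at 2 h and 10.14 at 6 h, against 5.59 and 5.99 on the DMSO arrays. Fosl2 rose by 2.24 ± 0.30, Spry1 by 2.21 ± 0.27, Dusp4 by 1.81 ± 0.23, and Rgs4 and Tmem212 by 2.14 and 1.76. Fosb (2.48) and Kcnh1 (2.21) rose from DMSO levels below 4. Ccnd2 rose by 0.66 ± 0.13 (adjusted p = 0.0165), Cdkn1a by 0.33 ± 0.06 (adjusted p = 0.0129), Fos by 1.38 ± 0.37 (adjusted p = 0.0435) and Egr1 by 1.65 ± 0.31 (adjusted p = 0.0139). Crem did not pass (0.73, adjusted p = 0.0537). Falls were led by the cytokine receptor gene Cntfr (-0.97), the lamin gene Lmnb1 (-0.78), the synaptic adhesion gene Nlgn1 (-0.75), Txnip (-0.70) and Zfp60 (-0.70), with Ptar1, Chd7, Rab36, Gsk3b and Aatk between -0.66 and -0.63. Other probe sets of Ptar1, Rab36 and Gsk3b differed in sign. Ins2 (0.05), Pdx1 (-0.09), Mki67 (-0.07), Irs2 (0.19) and the channel genes Cacna1c (-0.14) and Cacna1d (-0.10) did not pass.

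Of 38 immediate-early genes 20 rose and 0 fell with the combination, and of 30 CREB and cAMP targets 12 rose and 0 fell, Vgf by 1.41 and Fosl2 among them (23 and 17 up adjusted over the list alone). Both lists passed (adjusted p = 1.31e-13 and 1.07e-07, adjusted p = 0.136 and 0.155 with an estimated correlation). MAP kinase feedback genes had 9 of 21 up and 0 down (adjusted p = 2.52e-06, adjusted p = 0.0723 with an estimated correlation). Of 37 unfolded protein response genes 17 rose and 0 fell, and 25 rose adjusted over the list alone. Dnajb9 rose by 0.63, Ddit3 by 0.52, Hyou1 by 0.41 and Vldlr by 0.30 (median 0.23, adjusted p = 1.21e-10, adjusted p = 0.333 with an estimated correlation). Of 27 sterol biosynthesis genes 7 rose, Idi1 by 0.61 and Cyp51 by 0.47, and 0 fell (adjusted p = 1.09e-05, adjusted p = 0.552 with an estimated correlation). Of 59 G2/M genes 10 fell and 0 rose, the kinesin genes Kif20a by 0.34 and Kif22 by 0.28 among them (22 down adjusted over the list alone; adjusted p = 2.4e-13, adjusted p = 0.433 with an estimated correlation). G1/S genes moved both ways, Ccnd2 and Orc1 (0.44) up and 3 down, such as Rrm1 (-0.26) and Msh6 (-0.18) (adjusted p = 0.00535, adjusted p = 0.716 with an estimated correlation). Cell cycle inhibitors had 2 up, Cdkn1a and Gadd45g (0.29), and 4 down, Ccng2 (-0.54) and Sesn1 (-0.44) among them (adjusted p = 0.0126, adjusted p = 0.552 with an estimated correlation). Glycolysis and hypoxia genes had 7 up, such as Adm (1.39), P4ha2 (0.34) and Eno2 (0.31), and 2 down, Txnip included (adjusted p = 0.0327, adjusted p = 0.791 with an estimated correlation). By time the median of this list against DMSO was 0.26, 0.18, 0.16 and -0.03 at 0.5, 2, 6 and 24 h, from 1 array of each treatment.

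This comparison called 740 genes, 465 up and 275 down. Leaving out DMSO at 0.5, 2, 6 and 24 h gave 1165, 75, 92 and 331 genes, and leaving out the combination at those times gave 2219, 95, 105 and 111. Leaving out exendin-4 at 24 h gave 1366, and leaving out all arrays of 0.5, 2, 6 or 24 h gave 2015, 20, 25 and 105. Of 50 named genes called, 22 held with each array left out, Npas4, Tac1, Nr4a1, Fosl2, Dnajb9, Ddit3, Kif20a and Kif22 among them, while Ccnd2, Fos and Cntfr did not (adjusted p up to 0.0751, 0.0979 and 0.103). Lmnb1 was lost without the DMSO array of 6 h (adjusted p = 0.0508), and Cdkn1a without the 2 h array of DMSO or the 2 or 24 h array of the combination (adjusted p up to 0.0626).

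The combination was next set against BayK8644 alone, which asks what exendin-4 added. With limma 0 genes passed, 1372 had an unadjusted p under 0.05 (756 to 2479 with 1 array left out, lowest without the combination array of 24 h and highest without that of 0.5 h), and the fit on the arrays of those groups alone called 1. Among cAMP targets, 5 genes were higher at 4 of 4 times without passing. Their differences were Tac1 1.66 ± 0.43 (adjusted p = 0.205), Fosl2 1.45 ± 0.30 (adjusted p = 0.152), Nr4a1 0.94 ± 0.34 (adjusted p = 0.31), Crem 0.71 ± 0.21 (adjusted p = 0.254) and Pde4b 0.35 ± 0.08 (adjusted p = 0.184). Of the 30 CREB and cAMP targets 27 had positive differences and 6 rose adjusted over the list alone (median 0.20, adjusted p = 0.00259, adjusted p = 0.513 with an estimated correlation). The unfolded protein response list (median 0.09) was called with Atf6 at 0.23 and Herpud1 at 0.18, and the G2/M list with a median of -0.01 (adjusted p = 0.0397 and 0.0215, adjusted p = 0.825 and 0.858 with an estimated correlation). Without the combination array of 0.5 h the comparison called 330 genes, without that of 2 h it called 2, and without all arrays of 0.5 h it called 51.

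Against exendin-4 alone, the combination asks what BayK8644 added. Npas4 rose by 2.82 ± 0.21 (adjusted p = 7.82e-06, n = 4 arrays each), Spry1 by 2.53 ± 0.27, Fosb by 2.44 ± 0.35 and Rgs4 by 2.44 ± 0.40. Nr4a1 rose by 2.15 ± 0.34, Tac1 by 2.14 ± 0.43, Dusp4 by 1.65 ± 0.23 and Adm, the gene of the vasodilator peptide adrenomedullin, by 1.51 ± 0.19. S100a10 and Scel, the latter from below 4, rose by 1.43. The axon guidance receptor gene Robo2 fell by 1.19, Slc25a27 by 0.85, Gadd45a by 0.76, Txnip by 0.61 and Lockd by 0.57, and Plcxd3, 4921524J17Rik, Ripply3, Uvssa and 9130016M20Rik lay between -0.54 and -0.48. Immediate-early genes had 15 up and 0 down, CREB and cAMP targets 8 up and 1 down, MAP kinase feedback genes 8 up and 0 down and calcineurin and NFAT targets 3 up. These lists passed (adjusted p = 3.7e-15, 6.01e-05, 7.03e-07 and 0.00855, adjusted p = 0.125, 0.302, 0.0626 and 0.230 with an estimated correlation). Unfolded protein response genes had 3 up, Dnajb9 (0.52) among them, and 24 adjusted over the list alone. Sterol biosynthesis genes had 1 up, Idi1 (0.56), and 12 adjusted over the list alone. Glycolysis and hypoxia genes had 4 up, Ldha (0.74) among them, and 1 down (adjusted p = 2.59e-08, 1.6e-05 and 0.00731 for these lists, adjusted p = 0.460, 0.552 and 0.716 with an estimated correlation). Cdc20, Kif22 and Prc1 fell in the G2/M list, and Gadd45a and Sesn1 fell and Gadd45g rose among inhibitors. Orc1, whose probe sets differed in sign as did those of Ddit3, rose by 0.49 in the G1/S list (adjusted p = 8.68e-10, 0.0327 and 0.0403 for these lists, adjusted p = 0.552, 0.600 and 0.804 with an estimated correlation). Of Fos (1.12), Ccnd2 (0.50), Cdkn1a (0.25) and Crem (0.18) none passed. The count was 200, 142 up and 58 down. Leaving out exendin-4 at 0.5, 2, 6 and 24 h gave 668, 35, 32 and 49 genes, and the combination at those times 1655, 35, 34 and 39. Leaving out DMSO at 2 h gave 118, BayK8644 at 2 and 24 h 116 and 127, and all arrays of 0.5, 2, 6 or 24 h 1582, 11, 13 and 31. Of 40 named genes called 15 held with each array left out, while Nr4a1 was lost without the exendin-4 array of 6 h (adjusted p = 0.0554) and Rgs4 without the combination array of 6 h (adjusted p = 0.0567).

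A test for non-additivity asked whether the combination differed from the sum of the single effects. With limma 0 genes passed, 0 of the 20 lists was called, and the count stayed at 0 with each array or time left out. At an unadjusted p under 0.05 there were 710, where chance gives 530, and between 520 and 1394 with 1 array left out, lowest without the BayK8644 array of 2 h and highest without the combination array of 0.5 h. Nr4a1 deviated from the sum by 0.10 ± 0.48, Fos by -0.07 ± 0.53, Crem by 0.15 ± 0.30, Ccnd2 by 0.01 ± 0.18 and Cdkn1a by 0.03 ± 0.09. Across the 10609 genes the effects of the agents, each taken over both levels of the other agent, correlated with r = 0.28 (Spearman 0.32), and 61.8% of genes had the same sign. All 16 arrays enter both effects. In 20 simulations with no effect and errors independent between arrays, the mean correlation was -0.0086 and 49.8% of genes had the same sign, and the covariance was -4.61e-05 against 0.00413 observed. With the BayK8644 effect taken from 2 of the times and the exendin-4 effect from the others, so that no array entered both, the correlation lay between 0.094 and 0.27. Genes are not independent replicates. Of the 515 genes that rose with BayK8644 over both levels of exendin-4, 347 had a positive exendin-4 effect, and of the 390 that fell 263 had a negative one. At 0.5, 2, 6 and 24 h the Pearson correlation was 0.23, 0.18, 0.17 and 0.07. The Spearman correlation was 0.09, 0.20, 0.23 and 0.09, and 52.5, 56.4, 58.7 and 54.0% of genes had the same sign. The order of the times thus depended on the measure. The agent effect correlation changed to 0.40 and 0.44 without the 0.5 h array of DMSO and of the combination, and to 0.12 and 0.087 without that of BayK8644 and of exendin-4. The simulated correlations were 0.090 and 0.091 without the former arrays, and -0.11 without either of the latter.

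**Figure D3:**
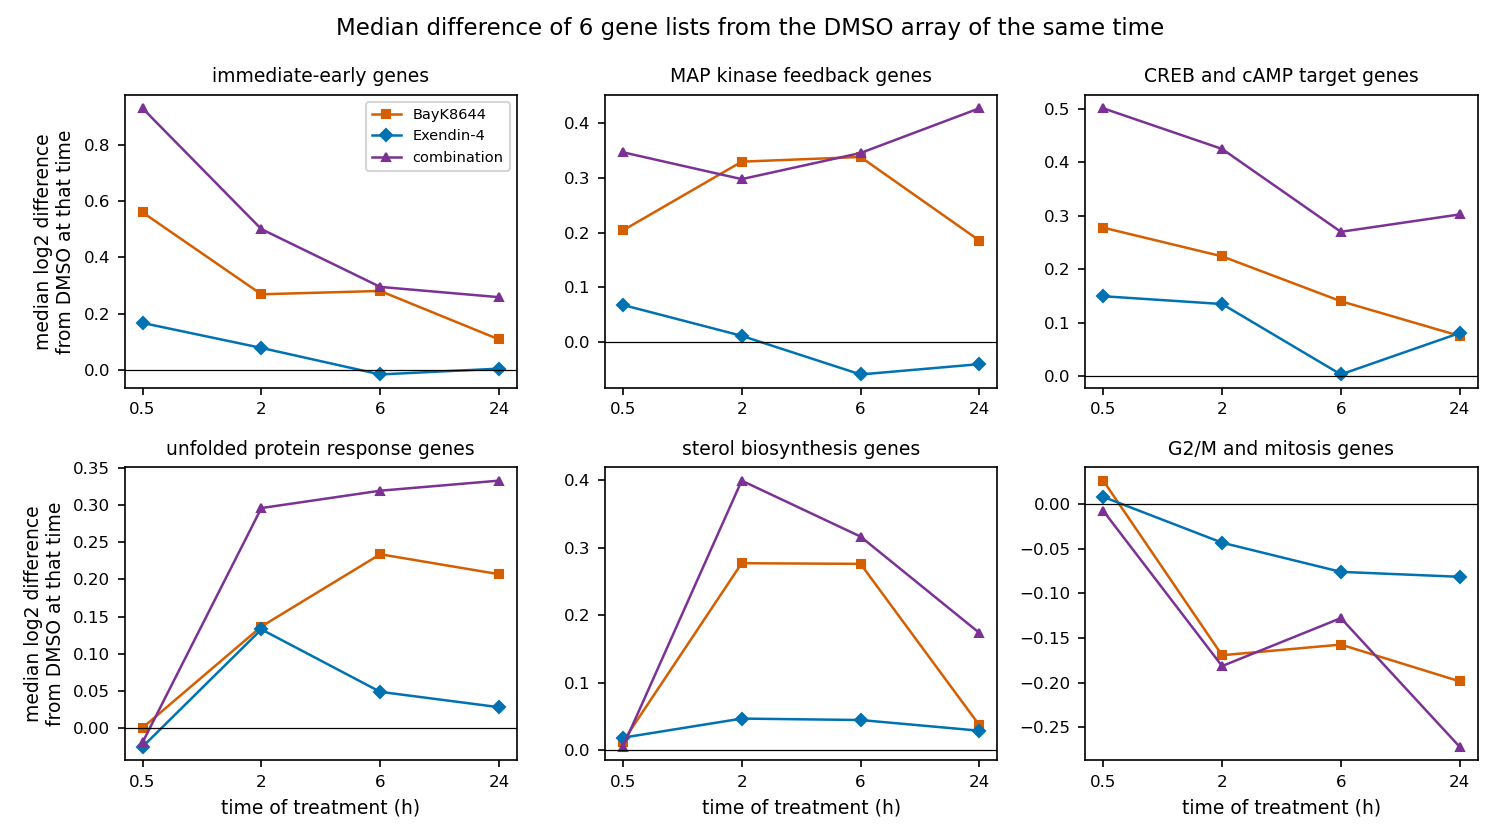
Median log2 difference of 6 gene lists from the DMSO array of the same time (vertical axes) against time in h (horizontal axes, evenly spaced), 1 point per array. The immediate-early list stands at 0.93 at 0.5 h with the combination and 0.56 with BayK8644, and the unfolded protein response list reaches 0.33 with the combination at 24 h.

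BayK8644 and exendin-4 were also compared with each other. Npas4 was 2.76 ± 0.21 higher with BayK8644 (adjusted p = 3.07e-05, n = 4 arrays each), Spry1 2.63 ± 0.27, Rgs4 2.22 ± 0.40, Fosb 1.98 ± 0.35, Dusp4 1.46 ± 0.23 and Dusp6 1.33 ± 0.15. Adm, Rhou, Rflna and Maff were higher by 1.25, 1.16, 1.13 and 0.90. Gadd45a (-1.01 ± 0.11) and Pde4b (-0.73 ± 0.08), a cAMP-induced phosphodiesterase gene, were lower with BayK8644, as were Btbd11 (-0.85), 4921524J17Rik (-0.62), the interleukin receptor gene Il1r1 (-0.61), Lcp2 (-0.56), Txnip (-0.51), Cntrl (-0.47), Syt13 (-0.46) and Lct (-0.46). MAP kinase feedback genes had 6 of 21 higher and 0 lower, Spry2 (0.83) and Dusp5 (0.56) among them, and passed with the estimated correlation too (adjusted p = 2.93e-10, adjusted p = 0.0335 with an estimated correlation). Immediate-early genes had 8 higher and 0 lower, calcineurin and NFAT targets 2 higher, and CREB and cAMP targets 3 higher and 1 lower, Nfil3 (0.77) and Pde4b among them (adjusted p = 6.86e-16, 7.91e-05 and 0.0397, adjusted p = 0.124, 0.115 and 0.664 with an estimated correlation). The G2/M, G1/S and sterol biosynthesis lists were called with 0 members past the threshold (medians -0.09, -0.05 and 0.12) and the unfolded protein response list with Vldlr higher by 0.25 (adjusted p = 1.65e-06, 0.00319, 0.000123 and 3.32e-06, adjusted p = 0.646, 0.716, 0.591 and 0.552 with an estimated correlation). Nr4a1 (2.3-fold, adjusted p = 0.137), Egr1 (1.42, adjusted p = 0.0542) and Crem (-0.53, adjusted p = 0.295) did not pass. The count was 80, 52 higher and 28 lower. Leaving out BayK8644 at 0.5, 2, 6 and 24 h gave 203, 15, 18 and 24 genes, and exendin-4 at those times 270, 17, 13 and 37. Leaving out DMSO at 2 and 6 h gave 51 and 50, the combination at 0.5, 2 and 6 h 129, 48 and 49, and all arrays of each time 469, 12, 8 and 20. Npas4, Spry1, Dusp6, Dusp5, Trib1, Id1, Gadd45a, Pde4b and 4921524J17Rik held with each array left out, and the other 18 named genes called did not.

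The 4 arrays of 24 h were set against the 4 of 0.5 h for the change with time in culture, averaged over the treatments. Among cell division genes, 58 of 59 G2/M genes fell and 0 rose (median -0.76, adjusted p = 2.32e-56, adjusted p = 0.0734 with an estimated correlation). Birc5 fell by 0.93 ± 0.05, Ckap2l by 0.91, Kif22 by 0.86 and the topoisomerase gene Top2a by 0.69, of which other probe sets differed in sign. Of 51 G1/S and replication genes 40 fell and 1 rose, with Rrm2 at -0.94, Mcm10 at -0.85, Dscc1 at -0.66 and Tk1 at -0.55 (median -0.38, adjusted p = 2.18e-22, adjusted p = 0.124 with an estimated correlation). The proliferation marker Mki67 fell by 0.62 (adjusted p = 2.44e-06). Cdkn1a, a p53-induced inhibitor of cyclin-dependent kinases, rose by 1.39 ± 0.06 (2.61-fold, adjusted p = 2.96e-08), and so did Phlda3 (1.95 ± 0.12), another p53 target, and the receptor gene Eda2r (2.69 ± 0.16, from below 4). Ccnd2 rose by 0.75 ± 0.13, which was 0.15 with DMSO, 1.01 with BayK8644, 0.61 with exendin-4 and 1.25 with the combination. Further rises were those of Sec14l3 (2.22), Tmem212 (2.13), 1700007K13Rik (1.92), Mapkapk3 (1.74) and Dcxr (1.60), and from below 4 of Gria3, Kcnh1 and Hpgds (2.51, 1.83 and 1.69). With DMSO alone Kcnh1 changed by 0.17, Hpgds by 0.14 and Tmem212 by 0.53, and Sec14l3, 1700007K13Rik, Mapkapk3, Dcxr and Gria3 by 2.03, 1.58, 1.21, 1.2 and 2.30. Early response genes, high at 0.5 h with the agents, fell: Egr1 by 1.60, Fos by 1.54, Nr4a1 by 1.46 and Fosb by 1.40. With DMSO alone these changed by -0.25, -0.06, 0.06 and -0.20. Falls were also seen for Pcdh8 (-1.73), Usp2 (-1.71), Iqgap3 (-1.38), Hs3st1 (-1.30), A930006K02Rik (-1.28), Brip1 (-1.27) and Poc1a (-1.25). With DMSO alone these changed by -0.74, -0.77, -0.98, -0.99, -2.20, -0.82 and -0.43. In the immediate-early list 17 of 38 fell, Klf6 (-0.39) among them, and 1, Plk2 (0.34), rose (adjusted p = 0.000374, adjusted p = 0.552 with an estimated correlation).

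Of 31 secretory granule genes 13 rose between 0.5 and 24 h, Ptprn by 0.80, Chgb by 0.49 and Scg5 by 0.33, and 2 fell (adjusted p = 0.00106, adjusted p = 0.125 with an estimated correlation). Unfolded protein response genes had 9 up, such as Ddit3 (0.40), Atf5 (0.32) and Vldlr (0.33, with probe sets that differed in sign), and 3 down, Ppp1r15a (-0.51) among them (adjusted p = 0.00387, adjusted p = 0.716 with an estimated correlation). With DMSO alone Ptprn changed by 0.36 and Ddit3 by 0.18. Glycolysis and hypoxia genes had 10 up, Aldoa (0.76) and Eno2 (0.56) among them, and 2 down, Hk1 (-0.62) included (adjusted p = 0.0118, adjusted p = 0.725 with an estimated correlation). The count was 2500, 1126 up and 1374 down, and lay between 1729 and 2629 with 1 array left out. Of 48 named genes 47 held each time, and Kcnh1 was lost without the BayK8644 or the combination array of 0.5 h or of 24 h (adjusted p up to 0.105). The Actb 3' to 5' log2 difference was 0.62 at 0.5 h and 0.66 at 24 h with DMSO, 0.60 and 0.66 with BayK8644, 0.67 and 0.69 with exendin-4, and 0.67 and 0.77 with the combination.

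The lists named next gave no call in the 6 comparisons of treatments over all times. Against DMSO, BayK8644, exendin-4 and the combination left the 14 control genes used as references at medians of -0.01, -0.03 and 0.04 (adjusted p = 0.856, 0.273 and 0.817). The 27 calcium channel and calcium handling genes lay at -0.03, -0.05 and -0.02 (adjusted p = 0.983, 0.337 and 0.303). The 32 beta-cell identity genes had medians of -0.03, -0.02 and -0.04 (adjusted p = 0.101, 0.303 and 0.109) and the 30 insulin, IGF and AKT genes -0.07, 0.01 and -0.03 (adjusted p = 0.0877, 0.655 and 0.241). Medians of the 31 secretory granule genes were 0.01, -0.01 and 0.04 (adjusted p = 0.817, 0.89 and 0.861). Apoptosis and survival genes (19 measured) had adjusted p = 0.88, 0.824 and 0.702, and circadian clock genes (16 measured) adjusted p = 0.23, 0.943 and 0.861. Few markers of other cell types reached the filter. The 6 acinar and duct markers (adjusted p = 0.872, 0.553 and 0.231), the 6 alpha, delta and PP cell markers (adjusted p = 0.0727, 0.655 and 0.147) and the 2 mesenchymal, endothelial and leukocyte markers (adjusted p = 0.586, 0.905 and 0.644) gave no call.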

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

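Among the tests given here, the joint test over the 4 times, the comparison of effect sizes, the test for a shift with expression level and all counts of other splits of the arrays were chosen after the result was seen.

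Exendin-4 called 0 genes against DMSO with limma over all times, with 698 at an unadjusted p under 0.05. A single deviant array as the whole reason is argued against by the count of 0 called genes that remained without the exendin-4 array of 24 h. That array did lower the unadjusted count, which was 1103 without it, while the count was 432 without the DMSO array of 6 h, under the 530 that chance gives. An effect that changed with time and was counted as error was seen for Nr4a1. Its exendin-4 effect differed by -1.8967 between 24 and 0.5 h (limma, adjusted p = 0.000512). The joint test of the effect at the 4 times called 1 gene for exendin-4 and 520 for BayK8644, which gives no sign of many large effects of this kind. With 4 residual degrees of freedom, against 9 over all times, that test could miss smaller ones. For other genes this explanation stays open. The exendin-4 effects were smaller than those of BayK8644: with the error variance taken off, their SD over genes was 0.0629 against 0.145, a ratio of 0.432. Whether smaller effects are the whole reason for the count of 0 stays open. The doses and the level of the receptor, whose gene Glp1r lay at the floor of the array, could also bear on this and were not tested.

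Eda2r, Phlda3, Ccng1 and Cdkn1a, which p53 is known to induce, were higher at 24 h than at 0.5 h, by 2.69, 1.95, 1.17 and 1.39, and this pattern was noticed in the data. Of 28 other measured p53 targets 16 rose and 1, Ppm1d, fell, with a median of 0.26 that lay at percentile 100 of 10000 random lists of like expression level. On the DMSO arrays alone the median was 0.28, so the pattern was there without either agent. A single array as the source is argued against, since with each array left out the 4 genes kept a share of at least 0.925 of their rise. A rise in p53 activity during the culture may therefore be a candidate explanation, while a loss of the viral T antigen that drives growth of R7T1 cells, medium change, cell density and the handling of the arrays of each time were not tested and stay open.

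G2/M and mitosis genes had lower values with BayK8644 than with DMSO, with a median of -0.13, and 0 of 59 passed over all genes. By time the median was 0.03 at 0.5 h and -0.17, -0.16 and -0.20 at 2, 6 and 24 h, from 1 array of each treatment. A shift that depends on expression level is argued against by random lists of like level, among which the median lay at percentile 0 and whose own median was -0.00. A single array is argued against too, since the highest median with 1 array left out was -0.1107, without the DMSO array of 24 h. The list test itself was lost with an estimated correlation (adjusted p = 0.460), so members that vary together across arrays may account for the call, and this stays open beside an effect of BayK8644 on the share of dividing cells.

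The arrays of each comparison were also split into other groups by exchanging treatments within times, which the model treats as blocks, and for 24 h against 0.5 h by exchanging times within treatments. This gives 8 splits, the real one included, too few for a share under 0.05. For BayK8644 against DMSO 1 of 8 splits, the real one, called as many as 89 genes, and the highest other called 0. For BayK8644 against exendin-4 it was 1 of 8 (80 genes, highest other 0), for the combination against DMSO 1 of 8 (740 genes, highest other 217) and for 24 h against 0.5 h 1 of 8 (2500 genes, highest other 0). For the combination against exendin-4, 2 of 8 splits called as many as the real 200. The other was the exchange of the arrays of 0.5 h, with 548 genes. Since time is a block, this points to a difference between the treatments at 0.5 h unlike that of later times. That split keeps the real labels at 2, 6 and 24 h, so it still holds the treatment difference of those times. The count of splits therefore cannot tell whether the 200 calls stand out. Where the real count was 0 each split calls at least as many, so the count of splits decides nothing there: 8 of 8 for exendin-4 against DMSO (highest other 1), 8 of 8 for the combination against BayK8644 (highest other 0) and 100 of 100 drawn splits for non-additivity. In the last the highest called 1380 genes in a split that grouped arrays mostly by the presence of BayK8644, a structure of the samples.

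Within a treatment the 4 arrays differ in time, and 15 of 84 groups of 4 held an array whose gap to its nearest neighbour took an unusually large share of the range, where chance flags about 1 in 20 groups (4.2 here). At 0.5 h Fos stood apart with BayK8644 (share 0.9132, 12.69), exendin-4 (0.8571, 10.54) and the combination (0.9281, 13.13), and Egr1 did so in the same treatments (0.8506, 0.9445 and 0.8857). At 24 h Mki67 was lower than at the other times with DMSO (0.8919, 13.11), BayK8644 (0.9341, 13.08) and the combination (0.8891, 12.97). The DMSO arrays also held a low Irs2 at 24 h (0.8668, 9.17), a high Ins2 at 6 h (0.9078, 15.78), a high Ccnd2 at 24 h (0.9431, 12.68), a high Rcan1 at 0.5 h (0.9886, 9.83) and a low percentage of probe sets at the filter level at 2 h (0.9497, 46.6%). Rcan1 was low at 24 h with exendin-4 (0.8519, 9.46).

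The effect of BayK8644 at 24 h differed from that at 0.5 h for Fos by -2.2265 (adjusted p = 0.000317), for Egr1 by -1.9511 (adjusted p = 0.0039), for Nr4a1 by -1.1835 (adjusted p = 0.0039) and for Ccnd2 by 0.7491 (adjusted p = 0.00437). The effect of exendin-4 on Nr4a1 differed by -1.8967 (adjusted p = 0.000512). Over all genes tested, 104 differed in this way for BayK8644, 60 higher and 44 lower at 24 h, and 1 for exendin-4. Among 2520 probe sets without exactly 1 gene symbol, which the comparisons did not use, 56 were called for the combination against DMSO, 37 up and 19 down.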

How the results depend on the processing

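The joint test over times and the effects taken from different times were chosen after the data were seen. Quantile normalization moved no count by over 1.5 times, but GCRMA already quantile-normalizes arrays, so this alternative is a weak test. Without the filter on low values, BayK8644 against DMSO called 44 genes, the combination against DMSO 272 and against exendin-4 44, BayK8644 against exendin-4 31, BayK8644 at 6 h 171, and exendin-4 at 0.5 and 24 h 3 and 2. With eBayes without trend and with robust settings these comparisons over all times called 52, 419, 106 and 48, BayK8644 at 2, 6 and 24 h 115, 140 and 314, and exendin-4 at 2 h 0. With all probe sets, BayK8644 against DMSO called 22, exendin-4 against DMSO 1, the combination against exendin-4 130, BayK8644 against exendin-4 43, 24 h against 0.5 h 4490, BayK8644 at 0.5 and 6 h 10 and 155, and exendin-4 at 2 h 0. The cause was not tested for these settings. From the arrays compared alone, which leave fewer degrees of freedom, BayK8644 against DMSO called 10, the combination against DMSO, BayK8644 and exendin-4 17, 1 and 12, and BayK8644 against exendin-4 7. With no time term, which leaves differences between times in the error, BayK8644 against DMSO called 10, the combination against DMSO 26 and against exendin-4 17, and BayK8644 against exendin-4 14. An estimated correlation kept 2 of 99 list calls, and the joint test called 520 genes for BayK8644 and 1 for exendin-4. With arrays or times left out, counts ranged from 5 to 591 for BayK8644 against DMSO, 20 to 2219 for the combination against DMSO, 0 to 330 against BayK8644, 11 to 1655 against exendin-4, 8 to 469 for BayK8644 against exendin-4 and 1729 to 2629 for 24 h against 0.5 h. For BayK8644 at 0.5, 2, 6 and 24 h they ranged from 6 to 24, 19 to 242, 29 to 411 and 113 to 1465, for exendin-4 at 0.5 and 2 h from 1 to 2 and 0 to 2, and they stayed at 0 for exendin-4 at 6 and 24 h, exendin-4 against DMSO and non-additivity. The agent effect correlation ranged from 0.0871 to 0.4417 with 1 array left out. It was 0.0936, 0.1775 and 0.1457 with the BayK8644 effect from 0.5 and 2 h, 0.5 and 6 h, and 2 and 6 h and the exendin-4 effect from the other times, and stayed near its value for the other choices of times. Without the filter, the test of the G2/M list for the combination against BayK8644 turned upward with its median still negative (-0.0105, adjusted p = 0.585), and the cause was not tested. Of 325 called results of named genes 112 passed under every alternative and 0 reversed. Values near the background floor limit what low genes can show.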

Other observations

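Genes named here were chosen after their values were seen, and no test of an explanation is reported in this part. Between 0.5 and 24 h other known p53 targets rose over the arrays of all treatments: Ddit4l by 1.21 ± 0.11 (SE, n = 4 arrays at each time, adjusted p = 4.05e-06), Trp53inp1 by 0.99 (adjusted p = 4.32e-07), Psrc1 by 0.95, Aen by 0.94, Zmat3 by 0.93 (adjusted p = 2.01e-07) and Polk by 0.86. Bbc3, which promotes apoptosis, rose by 0.60 and Mdm2, which restrains p53, by 0.38 (adjusted p = 0.00443). Sesn1 (0.06), Ddb2 (-0.07), Xpc (0.02) and Rrm2b (-0.04) did not pass.

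Further members of the lists passed. Nfil3, a transcription factor gene of the circadian clock, immediate-early and CREB and cAMP lists, rose by 0.64 with BayK8644 against DMSO (adjusted p = 0.0266), and Nfkbia, an inhibitor of NF-kappaB, rose by 0.36 (adjusted p = 0.0269). With the combination Vim, the vimentin gene, rose by 0.50 (adjusted p = 0.0436), Hnf4a by 0.31 and Pgk1 by 0.17, while Pax6, an islet transcription factor gene, fell by 0.29 and Gipr, which encodes the receptor of the incretin GIP, by 0.35.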
